A study of Mus musculus with 6 samples.

How the data were processed

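The series compares brain tissue, cerebellum in its title, of 3 wild-type and 3 Gb5 knockout mice on 6 arrays. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cRNA was made by the array maker's standard procedure. Per the labels' protocols, animals were littermates matched for age and sex, but the labels do not say which mice were littermates. The design text names biological replicates of mice. The authors' deposited table holds log2 values, 1 per probe and array. Per the submitters' processing notes, RMA and Partek were used, with no version and no test given; RMA corrects background, quantile-normalizes the arrays and summarises each probe set on the log2 scale, so a global change in RNA amount would not be seen. Scanner files, scan dates and detection calls were not used here, so batches could not be looked for beyond the values themselves and no probe could be called undetected.

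Groups were taken from the genotype in the sample labels, and each column was matched to its sample by name. The table holds 45101 probes, of which 64 are controls. The platform annotation pairs 34945 probes with 1 gene and 932 with several; 9160 have no listed gene and are unnamed here. Symbols were updated through Entrez identifiers in a RefSeq gene table (assembly GRCm38.p6), which held 34741 of the 1-gene probes; the other 204 kept the annotation's symbol. That table was used for names and gene order only. Each of 18193 genes was represented by its probe with the highest mean over all 6 arrays, so other probes of a gene are given where they differ. Genes were kept when this mean exceeded the 30th percentile of all probe means (4.70, log2), which left 14067 genes and removed 4126.

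Expression was compared with limma 3.58.1 in R 4.3.3: a linear model per gene, moderated by empirical Bayes with an intensity trend, knockout minus wild type, two-sided, with Benjamini-Hochberg adjustment over the 14067 genes and a threshold of 0.05. SE and 95% intervals come from this fit. Plain permutation of 3 against 3 arrays could not give p below 0.1, so no such test was used for single genes. The fit was tested on simulated data of 14067 genes with 200 changed genes in each of 10 runs: it recovered 36.4% of genes changed by 0.5, 84.4% changed by 1, 98.6% changed by 2 and 100% changed by 4 (log2), and 3.85% of its calls were false. Simulated genes varied independently, which real genes do not. Lists were tested with camera on the same genes, with a preset inter-gene correlation of 0.01 and adjustment over the 30 lists with at least 3 measured genes. In 10 simulated runs, also with independent genes, a list with every member shifted by -0.3 was called in 10, with 2 calls of other lists. Smaller shifts and correlated genes were not simulated, so these runs give neither power for smaller shifts nor the error rate on real arrays. An estimated correlation and fry, for movement in 1 direction and in either direction, were run beside it. fry does not compare a list with other genes.

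The 31 lists were fixed before the data were examined. They cover Gnb5 partners, other G protein subunits, Gi/o-coupled receptors with GIRK channels and adenylyl cyclases, Purkinje cells, mature granule cells, granule cell progenitors, immature neurons, inhibitory interneurons, Bergmann glia and astrocytes, myelinating oligodendrocytes, oligodendrocyte precursors, microglia, endothelial cells and pericytes, choroid plexus, meninges and fibroblasts, forebrain, brainstem and midbrain, blood, immediate early genes, synaptic scaffold proteins, axon guidance, glutamate and GABA-A receptors, voltage-gated channels, cholesterol synthesis, clock, glucocorticoid response, heat shock, interferon response with MHC class I, sex-linked genes, ribosomal proteins and oxidative phosphorylation. The last pair were taken by the start of the symbol, so ribosomal S6 kinases and assembly factors are included. List members without a single-gene probe above the filter were not analysed here. Genes named in the text are Gnb5 and its measured partners, the passing genes whose groups did not overlap (up to 12 in each direction), genes of the smallest unadjusted p to fill up to 24, and up to 4 passing or otherwise up to 2 members of each list with the largest change; other named genes were chosen after their values were seen.

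Neighbours of Gnb5 were the 100 tested genes on each side in gene order, compared with all other placed genes by Fisher's exact test. Alternatives were no filter, a filter at the 50th percentile, a second quantile normalization, subtraction of array medians, the mean of a gene's probes, every probe on its own, other variance models, array weights, each array left out, other thresholds, Xist as a covariate, other list tests and neighbourhoods of 50 and 200 genes. For the other variance models the list test was run on their z-scores. An alternative pseudocount was planned only for linear values and was not run.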

Results

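RNA from brain tissue of 3 wild-type mice and 3 mice lacking Gb5 was measured on 6 Affymetrix expression arrays of the single-colour type. The series title gives the tissue as cerebellum, and the labels describe the 3 arrays of each genotype as biological replicates. Gb5, encoded by Gnb5, is a G protein beta subunit that forms stable complexes with the R7 family of RGS proteins (Rgs6, Rgs7, Rgs9 and Rgs11) in neurons. The comparison of knockout with wild type addresses which cerebellar transcripts differ when Gb5 is absent. The deposited table held log2 signals for 45037 probes besides controls, with array medians from 6.48 to 6.57. Pearson's r over all probes lay between 0.991 and 0.997 for the 15 pairs of arrays, with a mean of 0.995 within a genotype and 0.994 between genotypes; probes are not independent replicates, and no 2 arrays held identical values. Precision is limited by the number of arrays: the median SE of a log2 fold change was 0.12, which gives a 95% interval of ± 0.27 for a typical gene.

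Knockout array 6 stood apart from the other 5 arrays in several signals. A probe of Xist, other than the one that represented the gene, read 6.64 (log2), against 11.1 to 11.3 on the others, and the Eif2s3y probe, for a Y-linked gene, read 11.80 against 3.19 to 3.43. Low Xist with bright Y-linked signal is the pattern of male tissue, and the other 5 arrays show that of female tissue. The labels describe sex-matched littermates, which these signals go against: by them, sex was not the same over the knockout arrays. On the same array the difference between the 3′ and 5′ control probes of Gapdh was 1.58, against 1.03 to 1.14 on the others.

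Gnb5 signal was nearly lost in the knockout arrays. The probe that represented it averaged 8.67 ± 0.15 (log2, SD, n = 3) in wild type and 3.32 ± 0.34 (SD, n = 3) in knockout. The log2 fold change was -5.35 (SE 0.18), with a limma adjusted p of 4.33e-06. The single arrays read 8.80, 8.51 and 8.70 in wild type and 3.65, 3.36 and 2.96 in knockout. The knockout mean lay at the 10.6th percentile of all probes. No detection calls were used here, so the fall is given as signal and not as an RNA ratio. A second Gnb5 probe was dim in both genotypes (4.88 and 4.24) and its log2 fold change of -0.64 did not pass when each probe was tested (adjusted p = 0.288). The labels do not place the deleted part of the gene relative to either probe.

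Of 14067 genes tested, 5 passed an adjusted p of 0.05: Guca1b was higher in knockout and Gnb5, Col12a1, Cap1 and Rsad2 were lower. Guca1b, which encodes a guanylate cyclase activator known from photoreceptors, rose from 5.01 ± 0.27 to 9.82 ± 0.19 (log2, SD, n = 3 each), a log2 fold change of 4.80 (SE 0.16; limma adjusted p = 4.33e-06). Its wild-type mean lay at the 33.5th percentile of all probes, and its other probe stayed dim in both genotypes, at 3.77 and 3.59. Cap1, an actin-binding adenylyl cyclase-associated protein, fell by 2.43 on the log2 scale (SE 0.24; limma adjusted p = 0.0143), from 10.51 ± 0.06 to 8.08 ± 0.56 (SD, n = 3 each). The second Cap1 probe had a log2 fold change of -1.81 and an adjusted p of 0.142 when each probe was tested. Rsad2, the interferon-inducible antiviral enzyme viperin, fell by 2.17 on the log2 scale (SE 0.22; limma adjusted p = 0.0143), from 9.51 ± 0.48 to 7.34 ± 0.11 (SD, n = 3 each), and a second Rsad2 probe had a log2 fold change of -2.20 (adjusted p = 0.0481 when each probe was tested). Col12a1, a fibril-associated collagen, fell by 2.09 on the log2 scale (SE 0.17; limma adjusted p = 0.00537), from 6.63 ± 0.31 to 4.53 ± 0.17 (SD, n = 3 each). The knockout level of Col12a1 lay at the 28.0th percentile of all probes, and its 3 other probes, all dimmer, had log2 fold changes of -0.02, -0.30 and -0.05. In each of the 5 genes all 3 knockout arrays lay on one side of all 3 wild-type arrays.

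**Figure D1:**
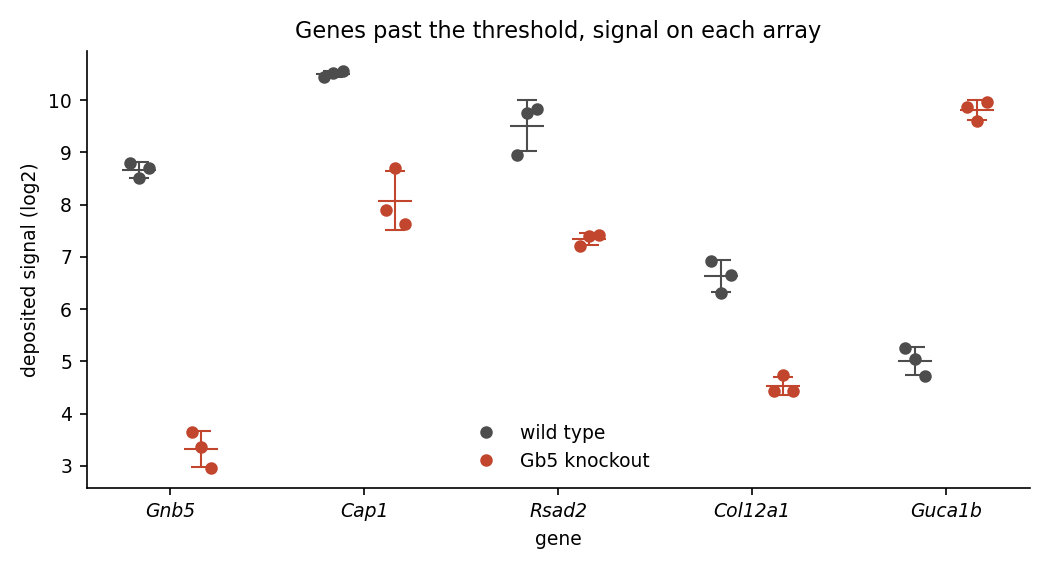
Deposited log2 signal (vertical axis) of the 5 genes that passed an adjusted p of 0.05, for the 3 wild-type arrays (grey) and the 3 knockout arrays (red). Each point is 1 array, dashes are group means and bars SDs; knockout Gnb5 points lie between 2.96 and 3.65 and wild-type points between 8.51 and 8.80, and Guca1b shows the opposite order.

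Gnb5 and Guca1b passed without any single array. Col12a1 did not pass without knockout array 6 (adjusted p = 0.0637), Cap1 without wild-type array 2 (0.136), wild-type array 3 (0.0661) or knockout array 6 (0.0637), and Rsad2 without those arrays (0.136, 0.0637 and 0.147) or without knockout array 5 (0.0731). Their log2 fold changes stayed near those of all 6 arrays in these cases: -2.04 for Col12a1, from -2.43 to -2.21 for Cap1 and from -2.21 to -2.02 for Rsad2. Col12a1, Cap1 and Rsad2 also did not pass with sex-linked genes left out and Xist as a covariate, where Gnb5 and Guca1b did. That covariate mainly marks knockout array 6, where Xist read 8.22 against 11.17 to 11.64 on the others. It is thus close to leaving that array out and not a separate check. The count of passing genes was 10, 3 and 3 without wild-type array 1, 2 and 3, and 8, 4 and 2 without knockout array 4, 5 and 6. Without wild-type array 1 the erythroid genes Alas2 and Slc4a1 and the genes Isg20, Apol11b and Tent5c were also lower. In 2103 of the 14067 genes the 3 arrays of one genotype all lay above those of the other, a share of 15%, against 10% by chance, and 261 genes had an unadjusted p under 0.01. In 2 of the 9 other divisions of the 6 arrays into 3 and 3 more genes did, 583 and 399.

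Below the threshold, the genes with the smallest p gave values only. Apol11b had a log2 fold change of -2.25 (adjusted p = 0.0577) and Tent5c one of -2.05 (adjusted p = 0.0817). Among lower values were the vascular anticoagulant receptor Thbd (-0.72), the transcription factor Foxc2 (-0.66), the matricellular gene Ccn3 (-0.92), Tm6sf2 (-0.82), Zfp493 (-0.61), Gm19531 (-1.11) and the dopamine transporter Slc6a3 (-1.33). Among higher values were the thioredoxin-binding gene Txnip (0.72), Hyi (0.85), Prr15 (0.62), Lysmd2 (0.76), Filip1 (1.09), D4Ertd617e (0.97), 4930429F24Rik (1.41), 5730403I07Rik (1.38), 1700028P14Rik (0.84) and 1700093K21Rik (0.87). Their adjusted p ran from 0.143 for D4Ertd617e to 0.206 for Zfp493. Without knockout array 4, 4930429F24Rik (adjusted p = 0.0373), Slc6a3 (adjusted p = 0.0274) and Fbxo30 passed, and without wild-type array 1 Apol11b (adjusted p = 0.000687) and Tent5c (adjusted p = 0.000789) passed.

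None of the 6 measured partners of Gnb5 passed, over all genes or adjusted over the list alone. Log2 fold changes were 0.54 for Rgs11, 0.36 for Rgs6, 0.26 for Rgs7, 0.16 for Rgs9, 0.02 for the orphan receptor Gpr158 and -0.19 for the membrane anchor Rgs7bp. Their 95% intervals reached from 0.11 to 0.98 for Rgs11, from -0.06 to 0.78 for Rgs6 and from 0.01 to 0.50 for Rgs7. They reached from -0.25 to 0.57 for Rgs9, from -0.27 to 0.30 for Gpr158 and from -0.49 to 0.12 for Rgs7bp. The unadjusted limma p was under 0.05 for 2 of the 6, Rgs11 and Rgs7, and for 1205 of all 14067 genes. The list as a group gave a median log2 fold change of 0.21 and a camera adjusted p of 0.315. The partners with values nearest to 0 changed sign: Rgs9 was -0.03 without wild-type array 1, and Gpr158 was -0.01 with array medians subtracted. No other partner changed sign in any alternative. Rgs6 read 0.16 without knockout array 5 and Rgs7bp -0.04 without wild-type array 1. Other G protein subunits (24 measured, none passing; Gna11 0.23, Gnb2 0.22, and 0.12 and 0.11 without knockout array 5) had a median of 0.05 and an adjusted p of 0.627. Receptors coupled to Gi/o, with GIRK channels and adenylyl cyclases (23 measured, none passing; Grm2 0.41, Grm8 0.31 and 0.12 without knockout array 5), had a median of 0.05 and an adjusted p of 0.669.

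Lists of cerebellar neurons held no passing gene, over all genes or adjusted over the list alone. Purkinje cell genes (21 measured) had a median log2 fold change of 0.06 and a camera adjusted p of 0.406, with Ebf2 at 0.52 and the calcium channel Cacna1g at 0.32. Mature granule cell genes (18 measured) had a median of 0.01 and an adjusted p of 0.674, with the NMDA receptor subunit Grin2c at 0.51 and the cadherin Fat2 at 0.35. Granule cell progenitor and proliferation genes (22 measured; Gli2 0.49, Barhl1 0.35) had a median of 0.09 and an adjusted p of 0.497. Inhibitory interneuron genes (15 measured; Sst 0.35 and 0.16 without wild-type array 1, Sorcs3 0.33 and 0.14 without knockout array 5) had a median of 0.12 and an adjusted p of 0.315. Immature neuron genes (19 measured; Tubb3 0.28, Nes -0.25) had a median of -0.02 and an adjusted p of 0.220. Without wild-type array 1 the Purkinje list (camera adjusted p = 0.00858) and the granule cell list (0.0442) were called higher and the immature neuron list (0.0182) lower. The granule cell list was also called higher without knockout array 5 (0.00829). These calls used the preset correlation. With an estimated correlation and all 6 arrays, the camera adjusted p of these lists was 0.896, 0.896 and 0.686, and single arrays were not left out there.

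Among non-neuronal lists, 2 of the 30 lists tested were called, both lower in knockout. Meninges and fibroblast genes (15 measured) had lower values in 13, a median log2 fold change of -0.11 and a camera adjusted p of 0.000102, which became an adjusted p of 0.684 with an estimated correlation. No member passed over all genes, and 1, Ccn3, passed adjusted over the list alone; the small leucine-rich proteoglycan genes Ogn and Fmod had values of -0.56 and -0.38. Genes of myelinating oligodendrocytes (17 measured) had lower values in 12, a median of -0.08 and an adjusted p of 0.00430, which became an adjusted p of 0.686 with an estimated correlation. No myelin gene passed, over all genes or adjusted over the list alone; the values of Ermn and Mal, genes of the myelin sheath, were -0.30 and -0.29 (Mal -0.17 without knockout array 5), and that of Mbp was 0.02. No list was called with an estimated correlation, where 1 list had an unadjusted p under 0.05, or by fry for movement in 1 direction, where 7 had. Both lists stayed called without any single array, with the meningeal median at -0.18 without knockout array 4, while the number of lists called was 8, 3 and 4 without wild-type array 1, 2 and 3, and 2, 5 and 4 without knockout array 4, 5 and 6. The same camera test called up to 9 lists when the 6 arrays were divided 3 and 3 in other ways.

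Genes of the interferon response and MHC class I went in both directions. Of 15 measured, Rsad2 fell and 14 did not pass; adjusted over the list alone 3 passed, Rsad2, the interferon signalling factor Irf9 (-0.54) and the class I gene H2-D1 (0.33). The median was -0.19 and the camera adjusted p 0.0710 (adjusted p = 0.696 with an estimated correlation), while fry for change in either direction gave an adjusted p of 4.27e-05, the only list it called. Interferon-inducible Oasl2 had a value of -0.58, and the class I pathway genes H2-K1 and Tap1 had values of 0.33 and 0.34. The camera test called this list lower without wild-type array 2 (adjusted p = 0.0237), wild-type array 3 (0.00158), knockout array 5 (0.0482) or knockout array 6 (0.0440).

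Blood genes (8 measured) had no passing gene over all genes and 3 adjusted over the list alone: the erythroid haem enzyme Alas2 (-2.08), the red cell anion exchanger Slc4a1 (-1.90) and Hbb-b2 (-0.60). The neutrophil genes S100a8 and S100a9 had values of 0.37 each. The median of the list was 0.02 while its mean was -0.45 and its test pointed lower, with a camera adjusted p of 0.159. Wild-type array 1 lay below the other wild-type arrays for Alas2, which had an SD of 0.92 in wild type and 0.26 in knockout. That array was also the lowest wild-type array for Slc4a1, Rsad2, Apol11b and Tent5c. A bright probe annotated to 4 globin genes averaged 13.53 in wild type and 12.77 in knockout (adjusted p = 0.193 when each probe was tested). The other probes annotated to several globin genes had log2 fold changes of -1.09, -1.06 and -1.09 and did not pass either. The single-gene probe of Hba-a2 read 9.06 and 9.13.

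**Figure D2:**
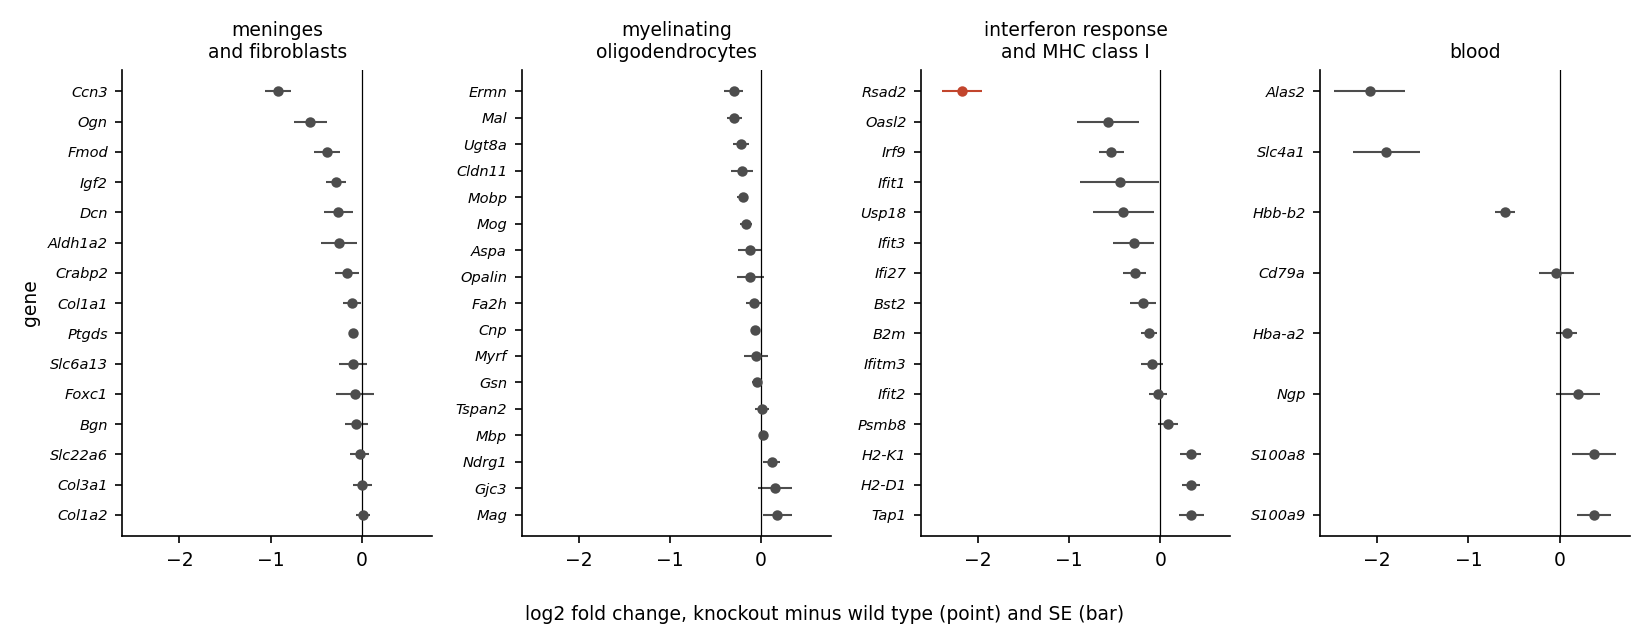
Log2 fold change, knockout minus wild type (horizontal axis), for each measured gene (vertical axis) of 4 lists: meninges and fibroblasts, myelinating oligodendrocytes, interferon response and MHC class I, and blood. Points are fitted values, bars their SE from 3 arrays per genotype and red marks Rsad2, which passed over all genes; the lowest meningeal values are those of Ccn3 (-0.92), Ogn (-0.56) and Fmod (-0.38), while Alas2 and Slc4a1 lie near Rsad2.

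The other lists of cell types and regions were not called and held no gene passing over all genes. Bergmann glia and astrocytes (20 measured; Gjb6 -0.26, Aldh1l1 0.22) had a median of -0.04 and an adjusted p of 0.222, oligodendrocyte precursors (15 measured; Bmp4 -0.38, Nkx2-2 -0.17 and -0.04 without knockout array 4) -0.08 and 0.159, and microglia (16 measured; Csf1r 0.22 and 0.11 without knockout array 6, Trem2 0.20 and 0.06 without wild-type array 2) -0.02 and 0.497, with a test pointing lower and a mean just above 0. Endothelial cells and pericytes (18 measured; Kcnj8 0.33, Myl9 -0.32) had a median of -0.04 and an adjusted p of 0.222, and forebrain genes (13 measured; Tbr1 -0.48, Crym 0.27) 0.07 and 0.850. Brainstem and midbrain genes (12 measured; Pou4f1 0.60) had a median of 0.01, a mean of -0.07 and a test pointing lower, with an adjusted p of 0.447; 1 gene, Slc6a3, passed adjusted over the list alone. Choroid plexus genes (15 measured; Ttr -0.56, F5 -0.53) had a median of -0.08 and an adjusted p of 0.402. Their signal differed between arrays of one genotype, with SDs of 1.13 for Ttr in knockout and 0.97 for F5 in wild type, and the list was called higher without wild-type array 1 (adjusted p = 0.0442) and lower without wild-type array 3 (0.0449) or knockout array 6 (0.0144). The precursor list was called lower without wild-type array 1 (0.00689) or knockout array 5 (0.00502), and the brainstem list without wild-type array 1 (0.0442). With an estimated correlation and all arrays, the camera adjusted p was 0.896 for the choroid plexus list and 0.831 for the precursor and brainstem lists. The list of sex-linked genes had 2 measured genes, Xist (-1.13, and -0.08 without knockout array 6) and Eif2s3y (2.83), neither passing, and was not tested.

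Lists of functions were also not called, and none of their genes passed over all genes. Clock genes (17 measured) had a median of 0.05 and an adjusted p of 0.497; Ciart (0.52) and Nr1d1 (0.47) passed adjusted over the list alone. Immediate early genes (17 measured; Nr4a1 0.62, Fos 0.33) had a median of 0.12 and an adjusted p of 0.850, glucocorticoid response genes (13 measured; Zbtb16 -0.38, Cdkn1a 0.29) -0.04 and 0.315, and heat shock and stress genes (15 measured; Sdf2l1 -0.28, Trib3 0.22) -0.04 and 0.220. Synaptic scaffold genes (28 measured; Dlg4 0.49, Dlgap4 0.34) had a median of 0.03 and an adjusted p of 0.864, glutamate and GABA-A receptor subunits (19 measured; Gabra2 -0.33, Grik5 0.26) -0.03 and 0.387, and voltage-gated channels (26 measured; Kcnc2 -0.34, Kcna2 -0.26) -0.01 and 0.493. Axon guidance genes (39 measured; Efna3 0.42, Unc5a 0.37) had a median of 0.01, a mean of 0.02 and a test pointing lower, with an adjusted p of 0.775. Cholesterol synthesis genes (17 measured; Sc5d -0.29, Hsd17b7 0.19) had a median of 0.02 and an adjusted p of 0.850, and oxidative phosphorylation genes (100 measured; Sdhaf1 0.38, Cox8b -0.37) 0.03 and 0.378. Ribosomal protein genes (53 measured; Rps25 -0.78, Rps15a-ps6 -0.46) had a median of 0.02 and an adjusted p of 0.864 with a test pointing higher and a mean just below 0. Values of single members that did not pass, here and in the other lists, often moved by more than 1.5 times without 1 array: without knockout array 4 Rps25 read -0.10, Nr4a1 0.31, Fos 0.06 and Sc5d -0.06, and without knockout array 5 Dlg4 read 0.22. In all these lists except the clock list no gene passed adjusted over the list alone.

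Genes near Gnb5 on its chromosome were compared with all other placed genes, because sequence of another strain can travel with a targeted allele. Of the 200 tested genes nearest to Gnb5, 1, Col12a1, passed, against 3 of 13789 others (two-sided Fisher's exact p = 0.0560). At an unadjusted p under 0.01, a threshold chosen after the data were seen, there were 9 of 200 (4.50%) against 247 of 13789 (1.79%; two-sided Fisher's exact p = 0.0114). The 9 were Gm19531 (-1.11), Lysmd2 (0.76), Bmp5 (-0.73), 5730403I07Rik (1.38), Col12a1 (-2.09), 4930429F24Rik (1.41), Filip1 (1.09), Me1 (0.62) and Nedd4 (0.23), and all lay within 50 tested genes of Gnb5. Without knockout array 6 no neighbour passed, Col12a1 having a log2 fold change of -2.04 there (adjusted p = 0.0637), and without knockout array 4 there were 2 (Fisher's exact p = 0.00408). Without wild-type array 1, 2 or 3 or knockout array 5, 1 neighbour passed, with Fisher's exact p of 0.122, 0.0284, 0.0284 and 0.0423.

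**Figure D3:**
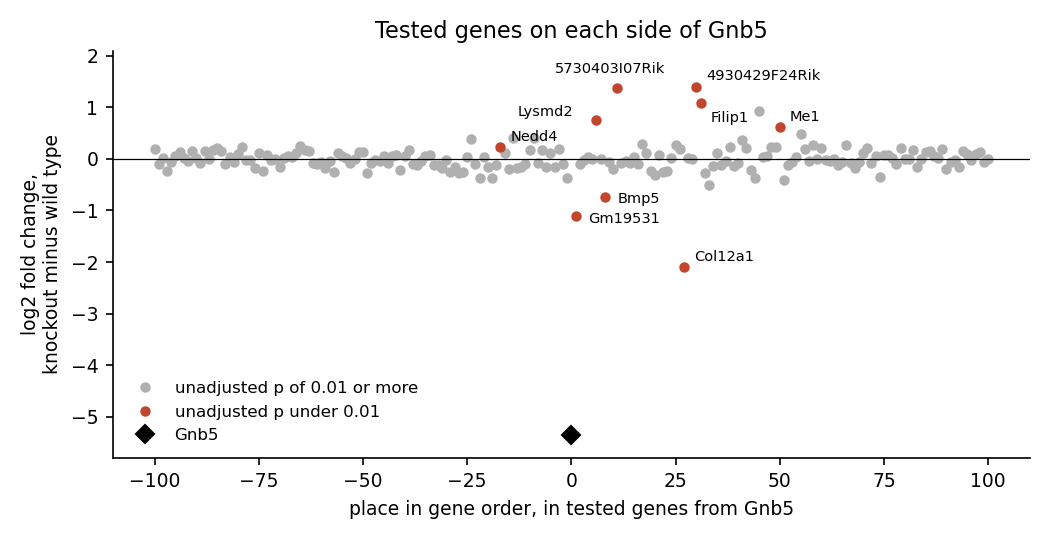
Log2 fold change, knockout minus wild type (vertical axis), of the 100 tested genes on each side of Gnb5, in gene order (horizontal axis, counted in tested genes). Red points are the 9 genes with an unadjusted p under 0.01, grey points the other neighbours, and the black diamond is Gnb5 at -5.35; the red points lie within 50 genes of Gnb5, with Col12a1 lowest at -2.09.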

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

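In this part the test on second probes, the count of neighbours at an unadjusted p under 0.01 and in other divisions of the arrays, and the test of the interferon members were chosen after the results were seen. The comparison of second probes with genes elsewhere, their directions, the Gnb5 window of 20 genes, the counts by distance and the demand that the erythroid median clear its bound by 1 SD were also added after first values were seen.

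Probes outside the comparison of genes carried a signal that differed between genotypes. With each of 45037 probes tested on its own, 10 passed, and 5 of these did not represent a gene: 2 probes without a listed gene (-3.63 and -2.96), 1 of Tmem30a (-3.16), 1 of Tmod3 (-2.66) and 1 of Rsad2 (-2.20), all as log2 fold change. Tmod3 and Tmem30a lie 6 and 36 annotated genes from Gnb5. The probe that represented Tmod3 had a log2 fold change of 0.03, while 3 further Tmod3 probes had -1.02, -0.87 and -0.32. The probe that represented Tmem30a had -0.01, and 3 further ones had -0.31, -0.07 and 0.02. Y-linked genes, of which only Eif2s3y was among the 14067 genes tested and none passed with each probe tested, were bright on knockout array 6: Eif2s3y read 11.80, Kdm5d 8.25 and Uty 7.14 (log2), and the highest readings on the other 5 arrays were 3.43, 3.26 and 2.78.

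A higher share of genes near Gnb5 than elsewhere had a small p value, at a threshold chosen after the data were seen. The Gnb5 window of 100 genes on each side held 9 genes with an unadjusted p under 0.01, which put it at the 95.8th percentile of 9985 such windows, between the bounds set for and against sequence of another strain kept around the targeted allele. The window of 20 genes on each side held 5 and lay at percentile 99.5 of 13185 windows, and all 9 lay within 50 genes. That goes with strain sequence and as well with a local effect of the targeted allele, and it recounts the same genes. Of 6 such neighbours with a second bright probe, 16.7% had one with the same direction and an unadjusted p under 0.05, against 35.2% of 105 genes elsewhere (two-sided Fisher's exact p = 0.662), and by direction alone 6 of 6 had one, against 90 of 105, so probe binding in place of RNA level cannot be told apart from a change in RNA. The bound first set for probe binding, a share of 50% or less, was met, but genes elsewhere met it too: second probes are dimmer, and genes picked by p favour the first probe. The real division of the arrays gave 9 such neighbours and the highest of the other divisions gave 8, among 261 and 583 genes with an unadjusted p under 0.01 in all; 1 of the 10 divisions, the real one, gave as many, and 10 are too few for a share under 0.05. Strain sequence and any local effect of the targeted allele both follow genotype and stay open, the latter untested. Tmod3 and Tmem30a were outside the second-probe test, because their representing probes had log2 fold changes of 0.03 and -0.01. Their probes differed widely: 1 of Tmem30a had -3.16 and its others -0.31 to 0.02, and those of Tmod3 ran from -2.66 to 0.03. The source of these differences between probes of a gene was not tested.

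Rsad2 fell in knockout arrays, and the erythroid genes Alas2 and Slc4a1 had log2 fold changes of -2.08 and -1.90 that did not pass (adjusted p = 0.247 and 0.249). Whether a lower interferon response was the whole source of the Rsad2 change could not be decided. The other 14 interferon members had a median log2 fold change of -0.16 (SD 0.32), more than 2 SD above -1.09, which is 50% of the Rsad2 change. But they ran from -0.58 to 0.34 and mix interferon-inducible genes with class I genes. The SD is thus a spread over unlike genes, and the bound assumes falls like that of Rsad2, which was not tested. Less erythroid RNA in the knockout tissue, as a difference in residual blood may give, stays open: an independent list of 26 erythroid genes, 13 of them above the filter in this tissue and 1 held by another list, had a median of -0.0356 (SD 0.14) and a camera p of 0.108. That median lay above the -0.05 set in advance as arguing against, but by less than the SD of the members. The measured members are also expressed in this tissue, Fech at 10.54 in wild type and 10.20 in knockout. Such a level would hide a small share of red cells. Wild-type array 1, the lowest wild-type array for Alas2, was also the lowest for Slc4a1 and Rsad2. Slc4a1 read 7.15, 8.66 and 8.64 in wild type and 6.11, 6.17 and 6.47 in knockout. Rsad2 read 8.95, 9.76 and 9.82 in wild type and 7.21, 7.39 and 7.42 in knockout. That shared order goes with a common source of these signals, which was not tested. In wild type and knockout, a probe of 4 globin genes read 13.53 and 12.77, a probe of 2 globin genes 12.90 and 11.84, and Alas2 9.03 and 6.95. The other probes of 2 globin genes had log2 fold changes of -1.09 and -1.09, and those of Hbb-b2 -0.60 and -0.72. None of these passed. The Hba-a2 probe went the other way, at 9.06 and 9.13, as did a dim Hba-a1 probe, at 3.40 and 3.50. Both were dimmer than the brightest globin probes, which limits what they say. A direct effect of the knockout was not tested.

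Meningeal and myelin lists were called lower in knockout arrays with the preset correlation and not with an estimated one (adjusted p = 0.684 and 0.686). The preset test also called the meningeal list in 3 of 9 other divisions of the arrays and the myelin list in 1. The lowest meningeal adjusted camera p among those divisions was 3.01e-06, below the 0.000102 of the real division. Knockout array 6, with its Y-linked signal and 3′ to 5′ difference, is argued against as the whole source of these calls, since without it the adjusted p of the preset test was 4.42e-08 for the meningeal list and 0.0143 for the myelin list; over the 6 arrays left out singly it ran up to 0.0114 and 0.0341. Fewer meningeal cells in the knockout tissue, from dissection or from the genotype, may account for the meningeal part: an independent list of 30 meningeal genes, 27 above the filter and 0 in another list, was lower in 22, with a median log2 fold change of -0.10 and a camera p of 0.000684, although the p was 0.0809 with an estimated correlation. Some falls in this list rested mainly on knockout array 5. On knockout arrays 4, 5 and 6 Cdh1 read 8.98, 8.22 and 8.92, and Slc6a20a 9.31, 8.83 and 9.30. Others, such as Slc47a1 and Mgp, were lower on every knockout array. The list was not tested without single arrays. The independent list also reached p under 0.05 in 3 of 9 other divisions of the arrays. The lowest camera p there were 6.03e-07 and 6.33e-06, both below the 0.000684 of the real division. The real division was thus not the one with the strongest shift, which limits what the test says about genotype. Its brightest members were uneven: Lgals1 read 12.14 and 12.11, Mgp 11.55 and 11.26, Nid1 10.95 and 10.87, S100a6 10.65 and 10.84, and Gjb2 10.57 and 10.29. The test of the independent list says nothing of the myelin list, for which a preset correlation that is too low and a structure among the arrays stay open.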

How the results depend on the processing

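The neighbour count at an unadjusted p under 0.01 was chosen after the data were seen. The 5 passing genes numbered 8 without a filter, 3 with the filter at the 50th percentile, 11 as probes with each of the 31511 probes above the filter tested separately, 2 with sex-linked genes left out and Xist as a covariate together and 261 at an unadjusted p under 0.01. The linear model without moderation called 0 genes (1009 at an unadjusted p under 0.05), where Gnb5 kept its log2 fold change of -5.35 at an adjusted p of 0.0761; a variance from 4 degrees of freedom per gene has less power by construction. Leaving out 1 array gave 2 to 10 genes, 2 to 8 lists and 0 to 2 neighbours. Gnb5 was removed by the filter at the 50th percentile and has no value there; over its 15 other alternatives it ranged from -5.51 to -2.99, the latter as the mean of its probes. Gene lists called were 4 with every probe tested separately, where blood (adjusted p = 0.0452) and heat shock genes (0.01001) were added, 0 with an estimated correlation and 0 by fry in 1 direction. The meningeal list, with a median of -0.11 that ran to -0.17 on the mean of probes and -0.20 with every probe tested separately, lost its call with the estimated correlation (adjusted p = 0.684) and by fry (0.131), as did the myelin list, with a median of -0.0759 (0.686 and 0.256). fry for either direction called neither (adjusted p = 0.156 and 0.235), and both kept the call under the other alternatives run for lists. Among neighbours of Gnb5, 0 passed with the filter at the 50th percentile, which removes Col12a1, and 0 without moderation, where no gene elsewhere passed either (Fisher's exact p = 1 for each). On the mean of a gene's probes 1 neighbour passed, Tmod3 in place of Col12a1 (Fisher's exact p = 0.0577). With every probe tested separately 3 probes passed (Fisher's exact p = 0.000112), within 50 genes on each side 1 (Fisher's exact p = 0.0283), within 200 genes on each side 1 (Fisher's exact p = 0.110) and at an unadjusted p under 0.01 9 (Fisher's exact p = 0.0114). The cause of these changes was not tested except where given. Signs turned only in values that did not pass: Gpr158 read -0.00992 with array medians subtracted and -0.0360 as the mean of its probes. Without single arrays it ran from -0.0910 to 0.0977, Rgs9 from -0.0338 to 0.27, F5 from -0.85 to 0.0360 and Ttr from -0.93 to 0.0887. Apol11b also passed without a filter (adjusted p = 0.0453), the interferon list was called on the mean of probes (adjusted p = 0.00212) and the oligodendrocyte precursor list with array weights (adjusted p = 0.00642). No paired analysis was possible because the labels number the arrays 1 to 6 and do not say which animals were littermates. Signal over background could not be judged without detection calls, which limits what the dim values of Gnb5, Col12a1 and Guca1b can say.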

Other observations

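In this part the count of lists with an estimated correlation in other divisions of the arrays was chosen after the results were seen; the other tests were written down before.

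Guca1b and Cap1 do not share a chromosome with Gnb5, and a further segment of other strain sequence was tested as a candidate source of their changes. Among windows of 20 genes on each side, the Guca1b window held 1 gene with an unadjusted p under 0.01 and the Cap1 window 2. The median window held 1 and the Gnb5 window 5. These counts put the Guca1b window at percentile 47.6 and the Cap1 window at percentile 84.3, both below the bound of 95 set in advance. Counts this low cannot tell a segment with few changed genes from none, so a segment around either gene stays open. A change limited to the gene itself, such as a variant under its probe, was not tested. The second Cap1 probe was also lower, by -1.81 (log2, SE 0.26, limma adjusted p = 0.142 with each probe tested). That argues against a variant under the representing Cap1 probe alone. The other Guca1b probe was dim in both genotypes and cannot tell. A direct effect of the lost Gnb5 product stays open and untested.

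The real division of the arrays called 5 genes and the highest of the other divisions called 4; 1 of the 10 divisions gave as many. For lists the real division called 2 and the highest of the others 9, and 8 of the 10 divisions gave as many. With 10 divisions no share under 0.05 can be had. With an estimated correlation the division that called 9 lists called 1, and the 8 other divisions beside the real one, which called 1 to 7, called 0. This goes with a preset correlation that is too low for these lists, but the power of the test with an estimated correlation was not measured; a structure among the arrays stays open.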
